A study of Arabidopsis thaliana with 6 samples.

How the data were processed

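Gene expression was measured by RNA sequencing in root samples of Arabidopsis thaliana, ecotype Col-0, the standard laboratory accession of this plant. Per the labels, seedlings were 3 days past germination and were kept for 1 h in liquid medium with 1 µM indole-3-acetic acid (IAA), the main natural auxin, or in mock medium. There were 2 groups of 3 samples, each made from about 100 roots. Per the labels, ribosomal RNA was removed before library construction and reads were paired-end, 100 bases long. The labels call the samples biological replicates and do not say whether they were grown and treated separately. The p-values of tests between the groups therefore rest on the spread between these samples only. The tests of families, of upstream hexamers and of neighbouring genes count genes instead, so their p-values measure no spread between samples.

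The deposited count table holds 32833 genes and gives raw read counts per gene, 1 column per sample, as whole numbers with no normalization. The series design mentions 2 technical runs per sample, and the deposited counts had them already combined, so runs were not compared. Per the submitters' processing notes, FastQC, STAR 2.5.2b, SAMtools and DESeq2 1.26.0 were used with the genome build TAIR10. The counting tool, the gene annotation and the strand setting are not given in the sources used here. Reads of antisense or overlapping genes, and reads shared by very similar gene copies, can therefore not be assigned with certainty to 1 gene.

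The authors also deposited a comparison of IAA with mock for 24598 genes. Per the file headers, it gives a mean normalized signal per gene, which is the mean of size-factor-scaled counts over the samples. Its log2 fold change and standard error are on the log2 scale, and the sign of the deposited log2 values is IAA over mock. The score in the authors' table is the Wald statistic, per the file headers. The p-value and the Benjamini-Hochberg adjusted p-value are also the authors'. All genes in this deposited table have a total count of at least 2, and genes left out of it have a total count of at most 1. A rerun of DESeq2 1.42.0 on the count table gave log2 fold changes that differed from the authors' deposited table by over 1e-06 for 0 genes.

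Library totals ranged from 20808439 to 20984444 counts. The main test was edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, robust) with TMM normalization, the filterByExpr filter, group as the only term and Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. It tested 19778 genes. Standard errors of log2 fold changes are approximate and were taken as the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, each count divided by the TMM-scaled library total and given per 1e+06 counts, given as mean ± SD with n = 3 per group. A gene with 1 to 3 counts in a group has its ratio given with an exact 95% interval, which covers counting error only.

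Before the data were examined, 24 gene lists with 373 entries were fixed by locus. For 1 entry (ERF109) the reference names the locus otherwise, and it was dropped. Each list with at least 3 tested members was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 23 lists. The test was repeated with an estimated correlation and with fry. Calls of members were counted over all genes tested and adjusted over the list alone. Shares of counts were compared with 2-sided exact permutation tests, whose smallest possible p with 3 against 3 samples is 0.1.

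The rule for named genes was fixed in advance. It took the 10 genes with the largest increase and the 10 with the largest decrease among called genes with an average log2 CPM of at least 0 and no overlap between groups. It added up to 4 called members of each list by smallest p, or the 2 most abundant members where none was called, and each called member of the lists of ethylene biosynthesis and of ethylene perception. Genes outside this rule are said to be so where they are named. Not every gene that the rule takes is reported here.

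On simulated data with the real means and library sizes, over 19624 genes, the edgeR procedure for the IAA comparison recovered 59 of 98 genes (60.2%) changed by a log2 of 1 and 85 of 95 (89.5%) changed by a log2 of 2. It made 18 false calls, 11.1% of its calls, a share above the adjusted p threshold of 0.05. Alternatives were RLE size factors, library totals, no low-count filter, a filter of at least 1 CPM and 10 counts in 3 libraries, DESeq2, limma-voom, the replicate number as a block, an adjusted p under 0.01, a minimum change of 2-fold, each library left out in turn, and tests without organelle genes. Symbols, gene types and positions come from the RefSeq annotation of TAIR10.1, matched by locus tag. This is the reference at hand, and the submitters' notes name TAIR10. Upstream sequence was the 500 bp before the annotated gene start. Exonic sequences of neighbours were compared with BLAST 2.17.0. Hexamer and family tests used scipy 1.17.1 in Python 3.11.15.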

Results

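Roots of 3-day-old Arabidopsis thaliana Col-0 seedlings were compared after 1 h in medium with 1 µM IAA or in mock medium. The series is concerned with mediators of the crosstalk between auxin and ethylene, a gaseous plant hormone. The deposited values were read counts per gene from 3 mock and 3 IAA libraries, each a pool of about 100 roots. Mock totals were 20954961, 20908916 and 20980747 counts, and IAA totals 20907285, 20808439 and 20984444.

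IAA was followed by a broad and mostly upward change in transcript levels. Of 19778 genes tested, 641 rose and 196 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 381 of the former and 92 of the latter changed at least 2-fold. The auxin-conjugating enzyme gene GH3.3 (AT2G23170, chromosome 2 from 9863855 to 9866562 in TAIR10.1) rose 187-fold, from 5.25 ± 1.05 to 985 ± 66.8 CPM (SD, n = 3). IAA5 (AT1G15580), an Aux/IAA repressor of auxin signalling, rose from a very low level, 0.0948 ± 0.00126 CPM, to 25.2 ± 8.34 CPM. Among the genes that fell, AT1G05650 went from 13.8 ± 4.44 to 0.48 ± 0.259 CPM and CYP90D1 (AT3G13730), which encodes a brassinosteroid biosynthetic P450 enzyme, from 26.7 ± 8.65 to 2.82 ± 1.82 CPM. Protein-coding genes made up 831 of the 837 calls. In all 837 the mock and IAA values did not overlap, while 22.1% of all tested genes had no overlap and chance gives 10%.

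The CYP90D1 call was absent without mock 1 or IAA 2. Without mock 1 there were 260 genes higher and 47 lower, without mock 2 370 higher, without IAA 1 433 lower, without IAA 2 326 higher and 48 lower, and without IAA 3 95 lower.

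The 10 largest increases included the ACC synthase gene ACS9 (AT3G49700), the zinc finger gene ZFP2 (AT5G57520), IAA5, GH3.3, RTFL13 (AT3G23635), which encodes a small ROTUNDIFOLIA-like peptide, the glutamate decarboxylase gene GAD4 (AT2G02010) and GH3.2 (AT4G37390). ACS9 had 1 count over the 3 mock libraries and 776 over the 3 IAA libraries, a ratio of 789.7 with a counting interval of 141 to 31232. The log2 change fitted by edgeR, an estimate separate from this ratio, was 9.16 or 571-fold (SE 0.53, edgeR adjusted p = 0.000151). ZFP2 had a log2 change of 8.30 (SE 0.32), from 0.0787 ± 0.0537 to 26.8 ± 5.20 CPM (SD, n = 3). RTFL13 went from 1 mock count to 179 IAA counts, a ratio of 182 with an interval of 32.3 to 7235. AT1G30190 went from 2 to 315 counts, a ratio of 160.3 with an interval of 44.0 to 1329, and these intervals cover counting error only. AT4G11340 rose 107-fold, AT3G47480 71.4-fold, GAD4 49.4-fold and GH3.2 42.7-fold, the last from 28.4 ± 1.18 to 1212 ± 274 CPM.

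The 10 largest decreases were led by AT1G05650 (log2 change -4.82, SE 0.40). GNC (AT5G56860), a GATA factor that promotes greening, fell by 3.29 on the log2 scale (SE 0.50), and the light-signalling factor gene PIF7 (AT5G61270) fell by 2.78 (SE 0.34), although both had low mock levels, 3.37 ± 1.95 and 1.58 ± 0.301 CPM. CYP90D1 fell by 3.24 (SE 0.49) and the expansin gene EXPA17 (AT4G01630) to 0.111 of its mock level, from 70.8 ± 26.5 to 7.88 ± 3.57 CPM (SD, n = 3). The other genes of this set were AT4G25250, AT3G07425, AT3G46400, AT5G25240 and AT3G44970, with log2 changes between -3.08 and -2.47. Calls were absent without mock 1 or IAA 2 for CYP90D1, without IAA 2 for GNC, without IAA 3 for EXPA17, without mock 2, mock 3, IAA 2 or IAA 3 for AT3G44970, and without any library except mock 3 for AT3G46400. Calls were also absent with limma-voom for AT3G46400 and AT3G44970, with the replicate block for EXPA17 and AT3G44970, with the library split as a term for AT3G46400 and with the photosynthesis share as a term for AT3G44970. AT1G05650 lies beside AT1G05660, which was chosen after its value was seen and also fell, with a log2 change of -2.12, and the exonic sequences of the pair were 90.9% identical over 1215 aligned bases, so their counts are uncertain as to which copy the reads came from. Transcripts of the photosynthesis list were also at a lower mean in the IAA libraries, 0.0596% ± 0.0511 of counts against 0.19% ± 0.149 in mock (exact permutation p = 0.3, n = 3 per group, smallest possible 0.1).

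**Figure D1:**
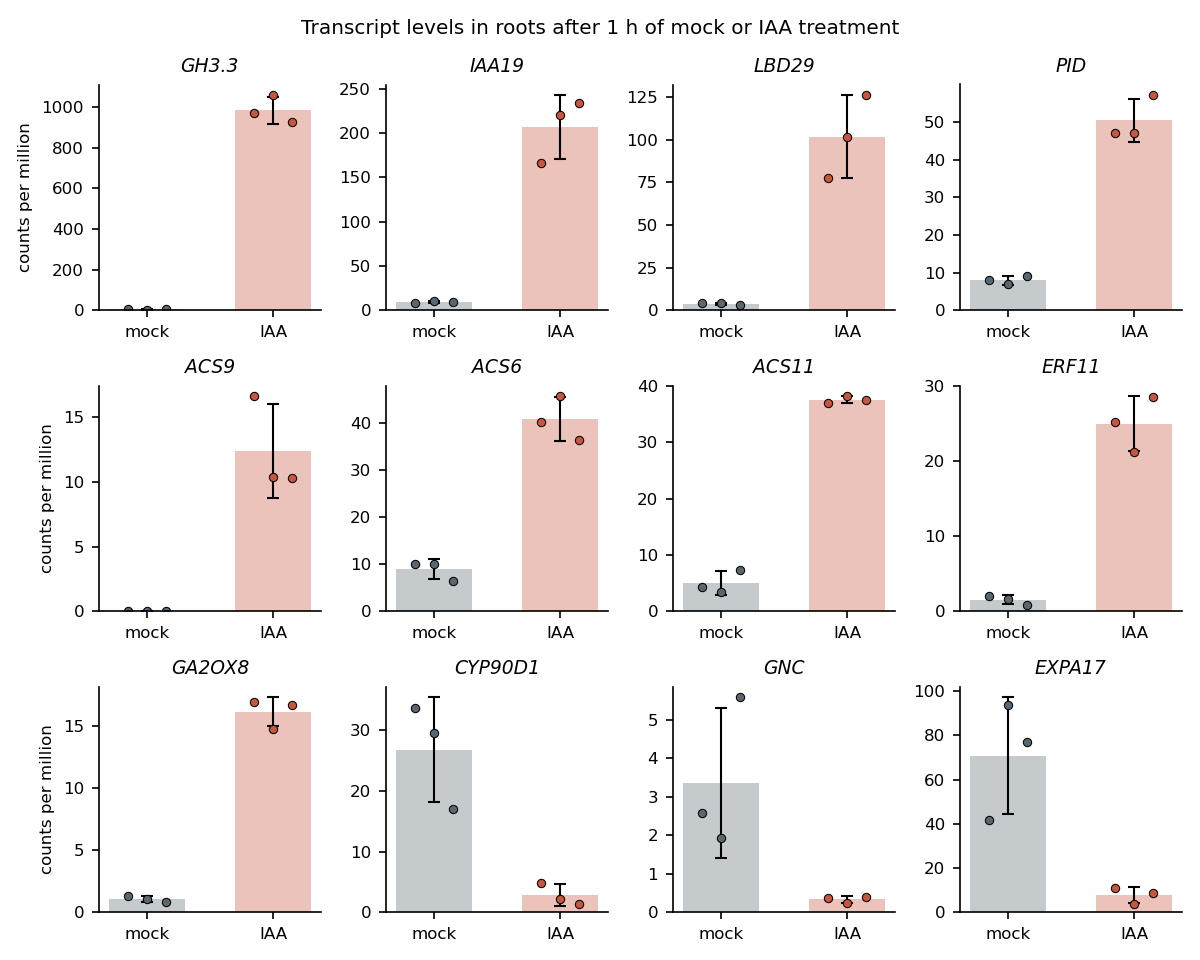
Transcript level in CPM (linear axis from 0) of 12 named genes in mock and IAA roots, with points for single libraries, bars for means and error bars for the SD (n = 3). In each panel the 3 IAA libraries lie on 1 side of the 3 mock libraries, for example at 985 against 5.25 CPM on average for GH3.3 and at 7.88 against 70.8 CPM for EXPA17. This follows from the choice of genes, since all 12 were called and no called gene had overlapping groups.

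In the core of the auxin pathway, 17 of 27 tested Aux/IAA repressor genes rose and 1 fell, and 21 rose and 1 fell when adjusted over the list alone. IAA19 rose 21.1-fold, from 9.80 ± 1.19 to 207 ± 35.7 CPM (SD, n = 3), IAA1 10.9-fold, IAA11 6.63-fold and IAA13 5.41-fold. The member that fell was IAA28 (log2 change -0.51, SE 0.11), named after its value was seen, and its call was absent with RLE size factors, the stricter filter, limma-voom, the replicate block and the library split as a term, at an adjusted p under 0.01 and at a minimum of 2-fold, and without mock 1, mock 2, IAA 2 or IAA 3. Of 6 GH3 genes tested, 5 rose, also when adjusted over the list alone. GH3.1 rose 14.7-fold, GH3.5 22.9-fold and GH3.6 15.1-fold, while GH3.17 had a log2 change of -0.22 and was not called, GH3.6 and GH3.17 being named after their values were seen. Both lists were called higher (camera adjusted p = 2.41e-21 and 5.34e-14), and both calls held with an estimated correlation (adjusted p = 0.0482 for each).

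Of 14 lateral root initiation genes tested, 9 rose and 0 fell in edgeR, and 11 rose when adjusted over the list alone. LBD29 rose 26.5-fold from 3.83 ± 0.782 to 102 ± 24.3 CPM (SD, n = 3), PUCHI 10.1-fold, MAKR4 9.05-fold and LBD18 6.71-fold, and LBD29, LBD18 and PUCHI encode transcription factors. Camera called this list higher (adjusted p = 3.87e-14, and adjusted p = 0.0482 with an estimated correlation).

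Among auxin transport genes, 7 of 19 rose and 0 fell in edgeR, and 10 rose when adjusted over the list alone. PID, a kinase gene whose product acts on PIN auxin efflux carriers, rose 6.27-fold (log2 SE 0.15), from 8.03 ± 1.18 to 50.4 ± 5.79 CPM (SD, n = 3), and the carrier genes PIN3 and PIN7 rose 2.56-fold and 2.46-fold. The list was called higher (camera adjusted p = 6.82e-09), and the call was lost with adjusted p = 0.0939 with an estimated correlation. Without mock 1, 3 members rose, and 4 rose without mock 2 or IAA 2 or with the replicate block. The PIN7 call was absent without mock 1.

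Auxin biosynthesis genes moved both ways. TAA1, the tryptophan aminotransferase gene of auxin synthesis, rose 2.72-fold from 31.3 ± 4.15 to 85.2 ± 26.8 CPM (SD, n = 3), and the flavin monooxygenase gene YUC6 fell by 1.75 on the log2 scale (SE 0.36). These were the only calls among 12 tested in edgeR, and 1 rose and 3 fell when adjusted over the list alone. The list was called lower (camera adjusted p = 0.0385), and the call was lost with adjusted p = 0.58 with an estimated correlation. The TAA1 call was lost without mock 1 or mock 2, and the YUC6 call without mock 1, mock 2, mock 3, IAA 2 or IAA 3, while 3 members fell without IAA 1. With library totals the YUC6 call was also lost, with the replicate block the TAA1 call was lost and 2 members fell, and with the photosynthesis share as a term or at an adjusted p under 0.01 both calls were lost. The list call was absent with fry (adjusted p = 0.277), with the library split as a term (0.107) and without mock 2 (camera adjusted p = 0.147) or IAA 3 (0.145).

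Among receptors and response factors, ARF19 rose 3.31-fold, from 67.0 ± 11.7 to 222 ± 7.68 CPM, and ARF4 1.78-fold, 2 of 21 tested with 0 that fell, and 3 rose when adjusted over the list alone. The receptor gene TIR1, chosen after its value was seen, had a log2 change of 0.11 and was not called. That list was not called (camera adjusted p = 0.0795), and leaving out mock 1, mock 2, mock 3 or IAA 2 left 1 call, the ARF4 call being absent, as it was with the photosynthesis share as a term. Without IAA 3 or with the library split as a term the list was called higher (camera adjusted p = 0.0162 and 0.031).

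The SAUR list, small auxin-up RNAs, was not called as a group. SAUR66 rose 15.6-fold, from 0.411 ± 0.0605 to 6.49 ± 1.68 CPM (SD, n = 3), SAUR24 9.61-fold and SAUR76 1.94-fold, while SAUR5 fell by 2.02 on the log2 scale (SE 0.26). In all, 3 of 21 rose and 1 fell, and 5 rose and 2 fell when adjusted over the list alone. The list median was -0.33 and its mean 0.09 on the log2 scale, and camera gave the direction up with adjusted p = 0.909. Without IAA 1, 4 members fell, and the direction in camera was down without mock 1, mock 2, IAA 1 or IAA 3 (adjusted p from 0.52 to 0.956).

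Of 14 HD-ZIP and other growth transcription factor genes, 4 rose and 0 fell in edgeR, and 8 rose when adjusted over the list alone. HAT2 rose 2.47-fold, from 64.7 ± 4.62 to 160 ± 18.6 CPM (SD, n = 3), MYB77 2.16-fold, HAT1 1.52-fold and T5L1 1.36-fold. Camera called the list higher (adjusted p = 0.000193), and the call was lost with adjusted p = 0.0861 with an estimated correlation. Without mock 1 or IAA 2, 1 member rose, and without IAA 3, 2 rose. Calls were absent without mock 1 or IAA 2 for MYB77, without mock 1, IAA 2 or IAA 3 for HAT1, and without any library except IAA 1 for T5L1. The HAT1 and T5L1 calls were also absent with the photosynthesis share as a term, and the T5L1 call with library totals or the replicate block.

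Ethylene biosynthesis genes bear on the question in the series title. ACS6, ACS9 and ACS11, which encode ACC synthases, the enzymes that make the ethylene precursor, rose, 3 of 15 tested with 0 that fell in edgeR. ACS6 (AT4G11280) rose 4.56-fold, from 8.96 ± 2.09 to 40.9 ± 4.63 CPM (SD, n = 3, edgeR adjusted p = 0.000897), and ACS11 (AT4G08040) 7.49-fold, from 5.01 ± 2.09 to 37.5 ± 0.58 CPM (edgeR adjusted p = 0.00163). ACS9 lies on chromosome 3 from 18434449 to 18436141, ACS6 on chromosome 4 from 6863979 to 6866116 and ACS11 on chromosome 4 from 4886962 to 4889224 in TAIR10.1. The ACC oxidase genes ACO1, ACO3, ACO4 and ACO5, which encode enzymes of the last step, were not called, with log2 changes of -1.23, -0.99, -0.72 and -0.38. Adjusted over the list alone, 3 rose and 1 fell, the latter being ACS5 (log2 change -1.59), named like these ACC oxidase genes after its value was seen. The list median was -0.14 and its mean 0.74, and camera gave the direction up with no call (adjusted p = 0.278). With fry, which tests whether the genes of a list move on balance 1 way and compares them with no other genes, the list was called higher (adjusted p = 0.0315). Without IAA 1, 1 member fell.

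Ethylene perception and signalling genes gave 0 calls of 15 tested in edgeR, against 3 higher and 1 lower at an unadjusted p under 0.05, 2 higher and 1 lower in DESeq2 and 0 in limma-voom. The receptor gene ERS1 was at 295.8 ± 15.4 CPM in mock and 284 ± 65.5 in IAA (SD, n = 3), and EBF2, whose F-box product targets the ethylene response factor EIN3, at 216.5 ± 31.9 and 238.5 ± 54.2 CPM. Both differences were within the spread between replicates. Adjusted over the list alone, 2 members rose, EIL1 and EBF1, named after their values were seen, with log2 changes of 0.47 and 0.40. The list was not called (camera adjusted p = 0.19). Without IAA 1 it was called higher (camera adjusted p = 0.0286) and 1 member rose, and without mock 3, 1 member fell.

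Among ethylene response transcription factor genes, 4 of 17 rose and 0 fell in edgeR, and 4 rose and 1 fell when adjusted over the list alone. ERF11 rose 16.1-fold, from 1.54 ± 0.614 to 24.9 ± 3.64 CPM (SD, n = 3), ERF6 2.33-fold, ERF115 9.24-fold and ERF114 5.71-fold, the last pair from mock levels of 0.158 CPM. EDF1 and EDF2, further factors of this list chosen after their values were seen, had log2 changes of 0.20 and 0.08 and were not called. The list was called higher (camera adjusted p = 0.00019), and the call was lost with adjusted p = 0.0999 with an estimated correlation. Without mock 1, 2 members rose, the ERF115 call being absent, and without mock 3, 1 fell. The ERF114 call was absent without any library except IAA 1, and with the replicate block or the photosynthesis share as a term.

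In the cytokinin list the 3 members that rose, of 14 tested, were the cytokinin oxidase genes CKX1, CKX3 and CKX5, which encode degrading enzymes. CKX5 rose 3.11-fold from 2.66 ± 0.766 to 8.30 ± 1.43 CPM (SD, n = 3), CKX1 4.96-fold and CKX3 5.53-fold, while the response regulator gene ARR5, chosen after its value was seen, had a log2 change of -0.05 and was not called. Adjusted over the list alone 4 rose, and the list was not called (camera adjusted p = 0.051). Without mock 1, 1 member rose, and without IAA 1, 2 fell. The CKX3 and CKX5 calls were absent without mock 1, and the CKX5 call without IAA 2. The list was called higher without mock 1 (camera adjusted p = 0.0284), IAA 2 (0.0353) or IAA 3 (0.00824), and with the replicate block (0.0385) or the library split as a term (0.00301).

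In the brassinosteroid and gibberellin list 4 of 15 rose and 2 fell, and 5 rose and 4 fell when adjusted over the list alone. GA2OX8 and GA2OX6, which encode gibberellin-inactivating oxidases, rose 15.2-fold and 3.38-fold, and GA2OX6 went from 20.4 ± 1.68 to 69.1 ± 1.69 CPM. BAS1, which encodes a brassinosteroid-inactivating enzyme, rose 1.53-fold. The brassinosteroid biosynthesis gene CPD fell by 0.63 on the log2 scale (SE 0.09), and of the remaining calls, named after their values were seen, the biosynthesis gene DWF4 rose 2.01-fold and ROT3 fell by 0.84. The list median was -0.05 and its mean 0.46, with camera direction up and no call (adjusted p = 0.331), while fry called it higher (adjusted p = 0.0408). Without mock 1, 2 of its members rose and 0 fell, without mock 2, 2 rose and 1 fell, and without IAA 2 or IAA 3, 0 and 1 fell. The BAS1 call was absent without mock 1, mock 2 or IAA 3 and with the replicate block or the photosynthesis share as a term, and the CPD call without mock 1 or IAA 2. Without IAA 1 the direction in camera was down (adjusted p = 0.936).

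**Figure D2:**
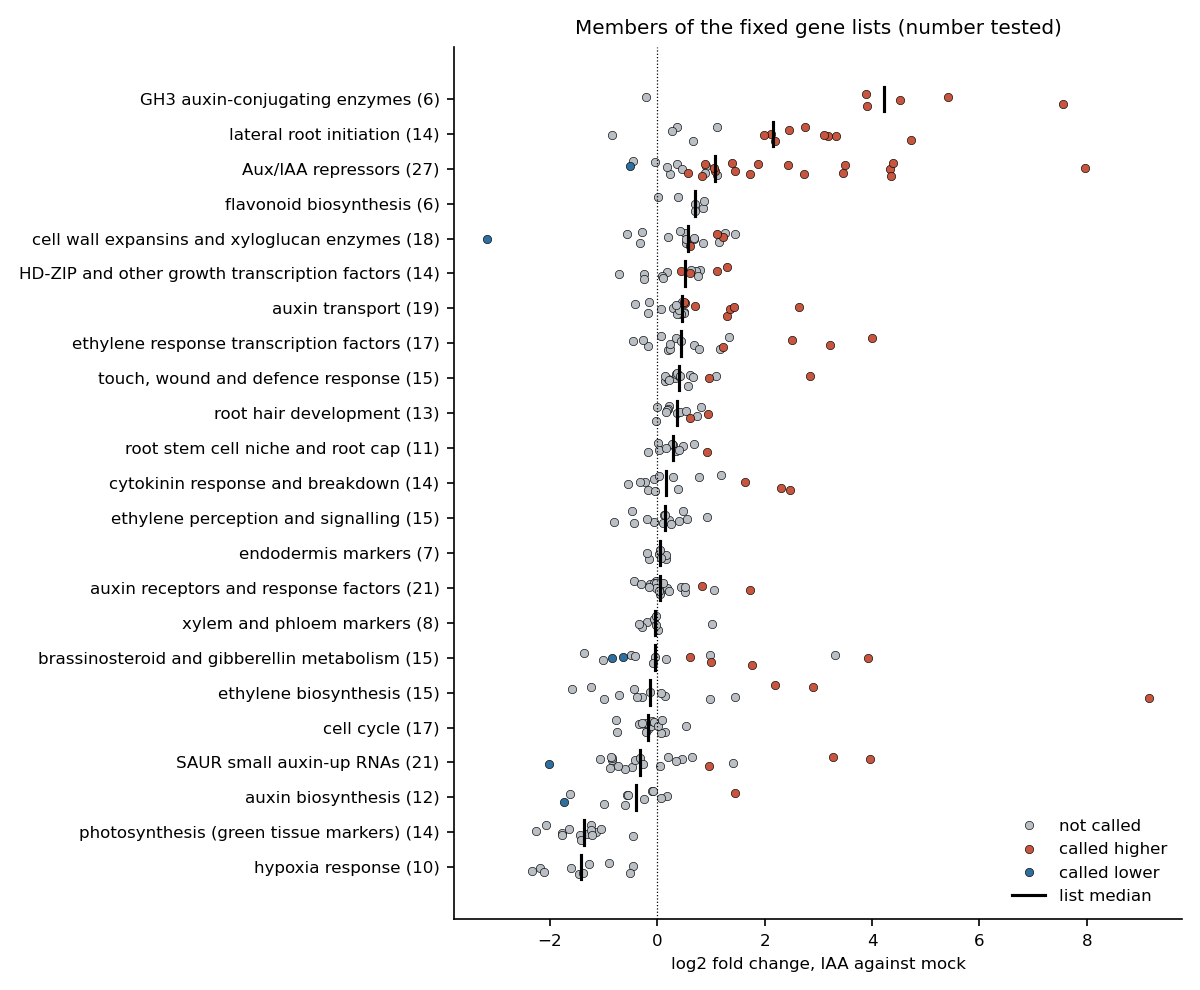
Log2 fold change, IAA against mock, of each tested member of the 23 gene lists, with called members in colour and the list median as a black line. The medians run from 4.22 for the GH3 genes and 2.16 for lateral root initiation to -1.36 for photosynthesis and -1.42 for hypoxia response, where 0 members were called by edgeR, 0 and 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

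In the cell wall list XTH19, a xyloglucan endotransglucosylase gene, rose 2.15-fold, from 48.1 ± 1.74 to 103 ± 8.38 CPM (SD, n = 3), and the expansin genes EXPA4 and EXPA7 2.32-fold and 1.53-fold, while EXPA17 fell. Of 18 tested, 3 rose and 1 fell, with 7 higher and 1 lower when adjusted over the list alone. Camera called the cell wall list higher (adjusted p = 0.0019), and the call was lost with adjusted p = 0.25 with an estimated correlation. Without IAA 1, 5 members rose and 2 fell, and without IAA 3, 0 fell. In the root hair list EXPA7 and RSL4, the latter a regulator of hair growth, rose, RSL4 by 1.92-fold, 2 of 13 tested with 3 when adjusted over the list alone. This list was called higher (camera adjusted p = 0.0028), and the call was lost with adjusted p = 0.156 with an estimated correlation. Without mock 1, 0 of these hair genes rose in edgeR (4 at an unadjusted p under 0.05, 3 in DESeq2 and 2 in limma-voom with all libraries).

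WOX5, which marks the quiescent centre of the root meristem, rose 1.90-fold, from 8.59 ± 1.52 to 16.3 ± 2.42 CPM (SD, n = 3), the 1 call among 11 stem cell niche and root cap genes. Adjusted over the list alone 3 rose. Camera called this list higher (adjusted p = 0.00978), and the call was lost with adjusted p = 0.548 with an estimated correlation. The WOX5 call was lost without mock 1, mock 2, IAA 2 or IAA 3, and without mock 3 there were 2 calls. The WOX5 call was also lost with the replicate block or the photosynthesis share as a term. The list call was absent with fry (adjusted p = 0.21) and without IAA 1 (camera adjusted p = 0.166).

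Cell cycle genes gave 0 calls of 17 in edgeR, also when adjusted over the list alone, with 3 lower at an unadjusted p under 0.05, 1 lower in DESeq2 and 0 calls in limma-voom. The kinase genes CDKA;1 and CDKB2;1 had log2 changes of -0.05 (SE 0.09) and -0.21 (SE 0.11), and CDKB2;1 was at 52.0 ± 1.86 CPM in mock and 44.9 ± 5.79 in IAA (SD, n = 3). The list median was -0.18, and camera called the list lower (adjusted p = 0.0191), a call that was lost with adjusted p = 0.144 with an estimated correlation. Without mock 3 the list call was absent (camera adjusted p = 0.0562), and without IAA 1, 1 member fell.

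Endodermis markers gave 0 calls of 7 and xylem and phloem markers 0 of 8 in edgeR, against 0 and 2 at an unadjusted p under 0.05, 0 and 1 in DESeq2 and 0 in limma-voom. CASP1 was at 158 ± 8.64 and 162 ± 38.2 CPM, PER64 at 126 ± 10.8 and 132 ± 7.10, XCP2 at 171 ± 22.5 and 149 ± 1.83 and XCP1 at 143 ± 18.5 and 141 ± 18.2 CPM. Adjusted over the list alone the counts were 0 for the endodermis and 1 higher, ACL5, named after its value was seen, for xylem and phloem. Neither list was called (camera adjusted p = 0.791 and 0.64), and the median of the xylem and phloem list, -0.04, and its test had the opposite sign to its mean of 0.01. The direction in camera was up without mock 1 for xylem and phloem (adjusted p = 0.744) and down without mock 3 (0.395) or IAA 2 (0.731) for the endodermis.

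Of 15 touch, wound and defence genes, the calmodulin-like gene TCH3 rose 7.18-fold, from 34.1 ± 7.09 to 245 ± 86.0 CPM (SD, n = 3), and the jasmonate repressor gene JAZ10 1.94-fold, with 0 that fell and 3 higher when adjusted over the list alone. This list was called higher (camera adjusted p = 2.59e-05), and the call was lost with adjusted p = 0.124 with an estimated correlation. Without IAA 1, 5 members rose, and without mock 1, mock 3, IAA 2 or IAA 3, 1 rose, the JAZ10 call being absent, as it was with library totals, the replicate block or the photosynthesis share as a term.

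Hypoxia response, photosynthesis and flavonoid genes differed between libraries within each group. ADH1, the alcohol dehydrogenase gene, was at 250.5 ± 219 CPM in mock and 49.8 ± 41.6 in IAA, and PDC1, which encodes pyruvate decarboxylase, at 229 ± 185 and 53.0 ± 46.6 CPM (SD, n = 3). The photosynthesis genes RBCS1A and LHCB1.3 were at 589 ± 490.2 and 446 ± 367 CPM in mock and at 123 ± 151 and 131 ± 68.9 in IAA. The flavonoid genes TT4 and CHIL were at 72.7 ± 53.1 and 23.1 ± 11.6 CPM in mock and at 133 ± 87.9 and 30.4 ± 12.5 in IAA. None of the 10 hypoxia, 14 photosynthesis or 6 flavonoid genes was called in edgeR, also when adjusted over each list alone, 1, 0 and 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Camera called the hypoxia and photosynthesis lists lower (adjusted p = 0.0275 and 0.00636) and not the flavonoid list (0.199), and these 2 calls were lost with adjusted p = 0.591 and 0.58 with an estimated correlation and were absent with fry (adjusted p = 0.503 and 0.459). The hypoxia call was absent without mock 1 (adjusted p = 0.147), mock 2 (0.25) or IAA 3 (0.175), the photosynthesis call without mock 3 or IAA 1 (0.166 for each), and the flavonoid list was called higher without mock 3 (0.0487) or IAA 1 (0.00709) and with the replicate block (0.0101). Without mock 3 or with the replicate block, 1 hypoxia gene fell. Seed storage transcripts, markers of embryo remnants, made up 5.89e-05% ± 1e-05 of mock and 4.95e-05% ± 1.99e-05 of IAA counts, and 0 of the 9 genes reached the level for testing.

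Between libraries, the first principal component (45.4% of the variance) separated the mock from the IAA libraries. The second (27.9%) split the libraries into mock 1, mock 2 and IAA 1 with negative values and mock 3, IAA 2 and IAA 3 with positive ones. Mock 1, at -7.40, lay between mock 2 (-35.1) and IAA 1 (-39.0) and the positive values of 32.7, 25.8 and 23.0, so it was not clearly in either set. With this library split as a term in the edgeR fit, 911 genes were higher and 459 lower, and 625 and 191 of the 641 and 196 calls remained. With the photosynthesis share as a term there were 438 higher and 134 lower, sharing 397 and 105 genes with the 641 and 196.

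**Figure D3:**
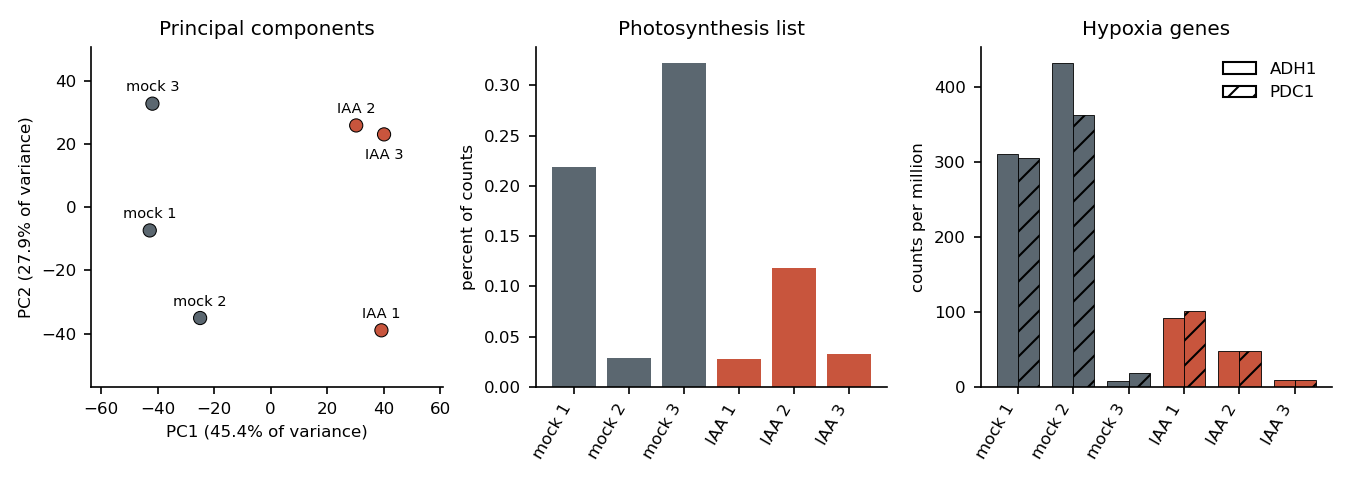
The 6 libraries on the first 2 principal components of log2 CPM (left), the percent of counts from the 14 photosynthesis genes (middle) and CPM of ADH1 and PDC1 (right), with mock in grey and IAA in red. The photosynthesis share was 0.219%, 0.0286% and 0.322% in mock 1, 2 and 3 and 0.0273%, 0.119% and 0.033% in IAA 1, 2 and 3.

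Over all lists, 10 of 23 were called higher and 4 lower with the preset correlation, and 3 higher and 0 lower with an estimated one, these 3 being the Aux/IAA, GH3 and lateral root lists. When the same 6 libraries were split in the 9 other ways into 3 and 3, camera with the preset correlation called 6 to 12 lists. Organelle genes took 0.0342% ± 0.0148 of counts in mock and 0.0606% ± 0.0335 in IAA (SD, n = 3 per group, exact permutation p = 0.3, smallest possible 0.1). Ribosomal RNA genes took 0.251% ± 0.0317 and 0.35% ± 0.151 (exact permutation p = 0.4), with 0.523% in IAA 3.

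The authors' deposited table listed 1087 genes as higher and 552 as lower after IAA at an adjusted p under 0.05. Of the 641 genes higher in edgeR, 639 were higher in the authors' deposited table, and of the 196 lower, 195 were lower there, with 0 in the opposite direction. For ACS6 the authors' deposited table gave a log2 fold change of 2.19 and for GH3.3 one of 7.55.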

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

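The fits without ribosomal RNA genes, with the library split as a term and with the photosynthesis share as a term were chosen after seeing the data. Against 641 genes higher and 196 lower, DESeq2 called 1087 and 552, an adjusted p under 0.01 left 272 and 39, a minimum of 2-fold left 381 and 92, the library split as a term gave 911 and 459, and the replicate block 462 and 149, of which 432 and 106 were shared with the 641 and 196. The strict threshold and the fold minimum call fewer genes by construction, and for the others the cause was not tested. Leaving out 1 library gave 260 to 839 higher and 47 to 433 lower. The calls with RLE size factors (635 and 193), library totals (573 and 186), no low-count filter (710 and 218), the stricter filter (647 and 188), limma-voom (612 and 181) and no organelle genes (643 and 196) stayed within 1.5 times, and 0 genes were called in the opposite direction in any of these fits. Of 80 named genes, 60 kept direction and call without mock 1, 64 without IAA 2, 68 without IAA 3, 70 without mock 2, 73 without mock 3 and 78 without IAA 1. The number was 62 at an adjusted p under 0.01, 69 with the photosynthesis share as a term (1 reversed), 70 at a minimum of 2-fold, 72 with the block, 76 with the library split (3 reversed), 77 with library totals, 78 with limma-voom, 79 of 79 with the stricter filter, and 80 with RLE size factors, DESeq2, no filter, and no organelle or ribosomal RNA genes.

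Values with no call changed sign, and the cause was not tested. XCP1 (log2 change -0.02) ranged from -0.12 to 0.0717 with 1 library left out and was 0.0904 with the library split as a term. CASP1 (0.03) ranged from -0.0922 to 0.22 and was -0.0744 with the split. ERS1 (-0.06) ranged from -0.16 to 0.12 and was 0.0163 with the photosynthesis share as a term, and EBF2 (0.14) was -0.0314 with the split. For lists, camera called 10 higher and 4 lower, against 3 and 0 with an estimated correlation, 11 and 1 with fry, 12 and 4 with the block and 12 and 3 with the split, and 10 to 12 and 2 to 4 with 1 library left out. Directions of uncalled lists turned, with adjusted p for SAUR of 0.52 to 0.956 with 1 library left out, 0.742 with the block and 0.651 with the split, for brassinosteroid and gibberellin of 0.15 to 0.936, for the endodermis of 0.211 to 0.985, and for xylem and phloem of 0.211 to 0.985 and 0.699 with the split.

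The labels do not say whether the replicate numbers pair the libraries. Correlations of residual log2 values between mock and IAA were 0.091, -0.449 and 0.202 for numbers 1, 2 and 3. Between different numbers they reached 0.327 (mock 2 with IAA 1). These values showed no pairing by number and cannot exclude it. The alternatives that treat the 2 technical runs separately were not run, because the counts hold 1 column per sample. Simulated changes of 1 on the log2 scale were recovered for 60.2% of genes, so smaller changes can be missed. The simulation drew each gene independently, without the differences between libraries that many genes share here, so recovery and false calls can differ in these data.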

Other observations

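The families, the adjustment over hexamers, the fits with the library split or the photosynthesis share as a term and the test of lower genes against green tissue were chosen after the results were seen. Genes were grouped by the stem of their symbol into 160 families with at least 8 tested members. Each was tested in both directions (320 Fisher's exact tests, one-sided, Benjamini-Hochberg adjusted), and 10 tests had an adjusted p under 0.05. These tests take the members of a family as independent. Members can change together, as the neighbours GSTU12 and GSTU11 or LBD16 and LBD17 did, so the adjusted p-values of families can be too small. Genes for small signalling peptides were among the families of these 10 tests. Of 18 CLE peptide genes 5 were higher (adjusted p = 0.0113), led by CLE44 (log2 change 4.01, SE 0.29, from 0.713 to 11.6 CPM), then CLE13, CLE16, CLE14 and CLE25, with log2 changes of 1.25, 1.13 and 1.00 for the last 3. Of 13 RTFL peptide genes 5 were higher (adjusted p = 0.00292), among them RTFL10 and RTFL19 with log2 changes of 1.89 and 2.11. Without mock 1 or IAA 3, 2 CLE genes were called, and without mock 2, mock 3 or IAA 2, 3. RTFL calls fell to 2 without mock 2, IAA 2 or IAA 3 and to 3 without mock 1.

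Among the LBD transcription factor genes 6 of 16 were higher (adjusted p = 0.000829), and 4 of 13 OFP genes (adjusted p = 0.0248), with OFP4 at a log2 change of 4.84 (SE 0.40) and OFP16 at 2.98 (SE 0.31). Of 24 GSTU genes, which encode glutathione transferases, 7 were higher (adjusted p = 0.000829) and GSTU27 was lower, and of 52 WRKY transcription factor genes 7 were higher (adjusted p = 0.0469). Among genes lower after IAA were 3 of 12 BGAL beta-galactosidase genes (adjusted p = 0.0113), with log2 changes of -0.94 for BGAL4, -0.68 for BGAL1 and -0.87 for BGAL2, 4 of 35 TBL genes (adjusted p = 0.0176, with TBL21 higher) and 3 of 23 AGP arabinogalactan protein genes (adjusted p = 0.0469), AGP7, AGP22 and AGP4, with log2 changes of -1.19, -1.25 and -1.38. The 17 Aux/IAA genes made up the remaining family (adjusted p = 7.79e-17). Under RLE size factors and library totals each family kept its direction. With the photosynthesis share as a term 0 BGAL genes were called lower and 1 higher in edgeR, and 1 TBL gene, 2 CLE genes and 3 WRKY genes were called in the family's direction. All 641 higher and 196 lower genes kept the sign of their change with this term, so calls were lost and directions did not turn. With the replicate block the calls in the family's direction were 1 BGAL, 1 TBL, 1 AGP, 3 GSTU, 3 CLE and 2 WRKY genes, and with the library split as a term 2 BGAL genes were called higher beside 3 lower. At an adjusted p under 0.01, 0 BGAL and 0 TBL genes, 1 AGP and 1 WRKY gene, and 2 GSTU, 2 RTFL and 2 CLE genes were left. Calls changed without single libraries, to 4 LBD genes without mock 1, mock 2, mock 3 or IAA 2, 2 OFP genes without mock 1, 1 GSTU gene without mock 1 and 3 without mock 2 or IAA 2, and 1 WRKY gene without mock 1 and 2 without mock 2, mock 3 or IAA 2. For lower families, BGAL calls went to 0 without mock 1, IAA 2 or IAA 3 and to 1 without mock 3, TBL calls to 0 without mock 1, IAA 2 or IAA 3 and to 1 without mock 2, and AGP calls to 1 without mock 1 or IAA 2 and to 5 without IAA 1. The counts of 0 without a library are from edgeR with 5 libraries, and with all 6, DESeq2 called 3 BGAL and 4 TBL genes lower and limma-voom 2 and 4.

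The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 641 genes higher and 196 lower, and the highest of the other splits 1 gene, whose direction is arbitrary since these splits have no treated side, so 1 of the 10 splits, the real one, gave as many. Each other split puts mock and IAA libraries in both sets, so a difference between treatments widens the spread within sets and lowers the number of genes called. The other splits are therefore no measure of the number of genes expected by chance. For lists the real split called 14 and the highest of the others 12, so again 1 of the 10 gave as many.

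One hypothesis was that genes higher after IAA carry an auxin response element in the 500 bp upstream. The element TGTCGG stood upstream of 10.4% of 635 higher genes and 8.17% of 18780 other tested protein-coding genes (odds ratio 1.303, Fisher's exact p = 0.0477, two-sided, 0.113 when adjusted over the 3 hexamers tested), and it ranked 91 among 2080 hexamers. For TGTCTC the shares were 23.3% and 21.3% (odds ratio 1.12, Fisher's exact p = 0.238, 0.238 when adjusted). For the related TGTCCC they were 10.1% and 8.05% (odds ratio 1.28, Fisher's exact p = 0.0756, 0.113 when adjusted). The test left the hypothesis open.

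The libraries mock 1, mock 2 and IAA 1 lay on the other side of the second principal component from mock 3, IAA 2 and IAA 3, with mock 1 in between. A bias by gene length is argued against, since its rank correlations across genes with this difference were -0.02969 in mock and 0.0768 in IAA. Those of GC content, -0.192 and -0.1018, leave that open. RNA degradation was looked at only through gene length, which it need not change where ribosomal RNA was removed, so it stays open. Green tissue carried over may contribute, as the photosynthesis list had median log2 differences of -1.94 in mock and -1.755 in IAA. The share did not follow the split in single libraries. Mock 1, at 0.219% of counts, lay above IAA 2 and IAA 3, and IAA 1 (0.0273%) was close to IAA 3 (0.033%). A different oxygen supply before harvest may also contribute, as a further list of 18 hypoxia genes had median log2 differences of 2.08 in mock and 0.6943 in IAA, with 15 of 18 higher in both groups. The split was less clear in single IAA libraries. ADH1 and PDC1, of the first hypoxia list, were at 92.4 and 102 CPM in IAA 1, 47.7 and 47.9 in IAA 2 and 9.25 each in IAA 3. IAA 2 thus lay between IAA 1 and IAA 3 for both genes. No further biological explanation was tested, since the design gives none for this split.

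Neighbouring genes were called in the same direction in 76 pairs, 63 higher and 13 lower, against a mean of 22.8 and at most 40 in 10000 shuffles (one-sided permutation p = 0.0001, the smallest these can give). Reads shared between near-identical neighbours are argued against, because 0% of the pairs were at least 95% identical. At a lower identity 12 pairs were alike, among them AT1G05650 and AT1G05660 at 90.9%, and for these 12 shared reads stay open. The shuffles did not allow for neighbours that are similar copies or members of 1 family, such as GSTU12 and GSTU11. Neighbours here are genes next to each other among those tested, and 45 of the 76 pairs lay on the same strand. Joint regulation of neighbours by IAA, and transcription running from 1 gene into the next, stay open and were not tested.

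Green tissue carried over with the mock roots was weighed as the whole source of the genes lower after IAA. With the photosynthesis share as a term the median log2 change of the photosynthesis list went from -1.36 to 0.01. This was set by the term, which is made from those genes. The median of the 196 lower genes went from -0.939 to -0.998 (quartiles -1.48 and -0.70), with a median adjusted p of 0.0458 in edgeR. Their changes thus did not follow the share, but this cannot decide the question. No called gene had overlapping groups, while the share did overlap, at 0.0286% in mock 2 and 0.119% in IAA 2. Genes that follow the share could therefore hardly have been called. Of the 196, 105 kept their call, as did 397 of the 641 higher genes. Over all 196, kept and ended calls together, the changes stayed about the same size and the edgeR p was larger (median 0.00122 against 0.000629). The 196 were called with the same 6 libraries, so green tissue, as the whole source or in single genes, stays open, beside a lowering by IAA.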
